A study of Mus musculus with 8 samples.

How the data were processed

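Single-cell RNA sequencing with 10x Genomics 3′ libraries was done on unsorted cells of early mammary tumors from MMTV-Wnt1 mice and from mice that also carried a dominant negative IGF1 receptor transgene (dnIGF1R/Wnt1). The series holds 8 libraries, 4 per genotype. Count matrices of 5 of them entered the tests, replicates 2 and 3 of Wnt1 and replicates 1, 2 and 4 of dnIGF1R/Wnt1, and the other 3 libraries were not analysed here. The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and barcode, without filtering or cell calling. Per the submitters' notes, they were made with Cell Ranger 7.0.1 and genome build mm10. Gene positions came from a GENCODE annotation of mm10, which held 32235 of the 32285 gene identifiers.

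The UMI totals were 96152512 and 66489183 in Wnt1 replicates 2 and 3, and 24493562, 12506995 and 57545595 in dnIGF1R/Wnt1 replicates 1, 2 and 4. Barcodes with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs were kept as cells. Scrublet as built into scanpy 1.11.5 marked 3 barcodes as doublets, between 0 and 0.07% of a library, so doublets were in effect not removed. Counts were scaled to 10000 per cell and log-transformed. The 36872 kept cells were clustered by the Leiden method at resolution 1 on 30 principal components of 2000 variable genes with 15 neighbors, without integration of batches and with seed 0. Log values, principal components and edge weights were rounded so that the result does not turn on the last digits of the arithmetic. This rounding was added after earlier clusterings that differed in nothing else had given other counts of genes in the test of basal-like against luminal-like cells, and it was fixed before its own results were seen. Further tools were igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, matplotlib 3.10.9 and Python 3.11.15.

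Clusters were named from 18 marker lists: luminal epithelial, basal epithelial, fibroblast, pericyte, endothelial, lymphatic endothelial, macrophage, dendritic, neutrophil, T, NK, B, plasma and mast cell, Schwann, adipocyte, erythroid and skeletal muscle. A name needed at least 3 markers that were seen in at least 5% of the cluster's cells and were at least 2-fold above the other cells. An epithelial cluster that met this for neither lineage was called epithelial, lineage not named, a cluster with strong markers of 2 kinds of cells was called mixed, and a cluster whose 10 leading genes contradicted its markers was left unnamed. These naming rules were revised after the clusters had been seen. The check of the leading genes was applied after gene test results had been seen. It left a cluster led by Acta1, Gal and Mia unnamed, which scored highest for skeletal muscle although 0 of those markers passed, and a version with that cluster among the epithelial cells was an added alternative. The lists not named in the results gave no class. The epithelial-like class joined luminal-like, basal-like and lineage-not-named cells.

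Counts were summed per library and class, since the library and not the cell is the replicate. A class entered with each library that held at least 20 of its cells and was tested with at least 2 such libraries per group. The labels give no more on the origin of each library than its number, and if some shared an animal the p-values would measure the spread between samples. Genes were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3 with TMM normalization, filterByExpr and the Benjamini-Hochberg adjustment at 0.05. Fold changes are dnIGF1R/Wnt1 over Wnt1, and levels are CPM, the counts scaled to library size by the cpm function of edgeR. The basal-like and luminal-like effects were compared by the interaction of class and genotype with library as a block. Shares of cells were tested with edgeR over 12 classes and with a two-sided exact permutation test, whose smallest possible p is 0.2 with 10 splits of 2 against 3 libraries.

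The 29 gene lists were IGF axis, Wnt target genes, ER stress and unfolded protein response, amino acid stress (ATF4) genes, oxidative stress response, cytokines and chemokines, epithelial adhesion, mesenchymal genes, extracellular proteases and inhibitors, matrix proteins, alveolar luminal and milk genes, hormone-sensing luminal genes, basal lineage genes, proliferation, MHC class I presentation, MHC class II presentation, interferon response, glycolysis and hypoxia, cholesterol and fatty acid synthesis, FOXO target genes, tissue dissociation stress, apoptosis and p53, oxidative phosphorylation, resident and lipid-handling macrophage genes, inflammatory macrophage genes, T cell cytotoxicity and activation, T cell checkpoint and exhaustion, fibroblast activation, and angiogenesis and endothelial activation. Lists with at least 4 measured members were tested with camera in limma 3.58.1 with the preset correlation of 0.01, adjusted over the lists of a class. The same lists were run with an estimated correlation and with fry. Camera compares a list with the other genes, directional fry asks whether its members move, on balance, one way, and mixed fry whether they change either way.

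Named genes were those past an adjusted p of 0.05 whose CPM separated all libraries of the groups, with a mean of at least 10 CPM, up to 10 per direction in epithelial-like cells and whole tumor and up to 5 elsewhere. Where none passed, the 3 per direction with the smallest p were named as not passing. Gene models without a proper name, mitochondrial, ribosomal protein, immunoglobulin, T cell receptor segment and hemoglobin genes, Xist and Y-linked genes were left out of the names. Wnt1, Igf1r, Insr, Igf1, Cdh1 and Cdh3 were always read, in whole tumor or epithelial-like cells and wherever they separated the libraries, and from each described list up to 4 members with the smallest p.

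The tests, filters, marker lists, gene lists, naming rule for genes and the first set of alternative settings were fixed before the data were examined. The pericyte-like and lineage-not-named classes were tested after their size had been seen. This first set was DESeq2 1.42.0, library size only in place of TMM, no filter on low counts, an estimated correlation in camera, looser cells (500 UMIs, 250 genes, 25% mitochondrial UMIs), stricter cells (2000 UMIs, 1000 genes, 10%), doublets kept, Leiden resolution 0.5, at least 50 cells per library and class, genes left out whose counts could come for over 25% from free RNA, shares of non-epithelial cells, and each library left out in turn. Free RNA was estimated from barcodes with 10 to 100 UMIs, scaled by markers a class should lack. This upper estimate is no proven bound. Its barcodes (4934 in Wnt1 replicate 3, 75090 in dnIGF1R/Wnt1 replicate 1) limit comparison of libraries. The 8 added alternatives were removal of doublets at 0.8% per 1000 barcodes up to 15%, removal of a loess trend (span 0.5) on genomic gene length, whole tumor without mixed clusters, the pair of classes named above, the cluster led by Acta1 kept, shares with that cluster and neutrophil-like cells out of the total and with the mixed clusters out too, and clustering with seeds 1 and 2. The setting with doublets kept adds 3 barcodes and so tests another clustering. Shares that join that cluster with epithelial-like cells or a mixed cluster with macrophage-like cells were computed after results had been seen, as were the shares by clustering, the makeup of classes by cluster and simulations of the interaction on all of its genes.

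The gene test was tested on simulated data with 200 changed genes per class at the depth and spread of these libraries. It recovered between 52 and 99% of genes changed 4-fold and between 1.02 and 34% of genes changed 2-fold. The share of calls that were false was 5.71 to 24.6% with each gene's own dispersion and 1.44 to 6.12% with the trended dispersion. DESeq2 recovered 25 to 77% of the changed genes and called 5 to 56 unchanged ones, 50 in whole tumor and 56 in epithelial-like cells. In 100 simulations of shares, a 4-fold change was called in 2% with 1 common dispersion and 35% with each class's own dispersion. The latter was added after the former had been seen. Simulated classes with under 5 cells in all libraries together were dropped. Intervals of single shares are exact 95% binomial and cover counting error only.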

Results

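Unsorted cells of early mammary tumors from Wnt1 (2 libraries) and dnIGF1R/Wnt1 mice (3 libraries) were profiled by single-cell RNA sequencing. The comparison asks which cells and genes differ when IGF1 receptor signalling is reduced. Wnt1 replicates 2 and 3 gave 5015 and 18630 kept cells with medians of 7950 and 1852 UMIs per cell. dnIGF1R/Wnt1 replicates 1, 2 and 4 gave 4722, 3026 and 5479 cells with medians of 2296, 2012 and 4303 UMIs. Wnt1 replicate 3 stood apart: its barcode curve had no clear step between cells and empty droplets, 65.1% of its UMIs lay in barcodes with at least 1000 UMIs, and 27.4% of its cells fell in mixed clusters, against 1.08 to 2.12% elsewhere.

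**Figure D1:**
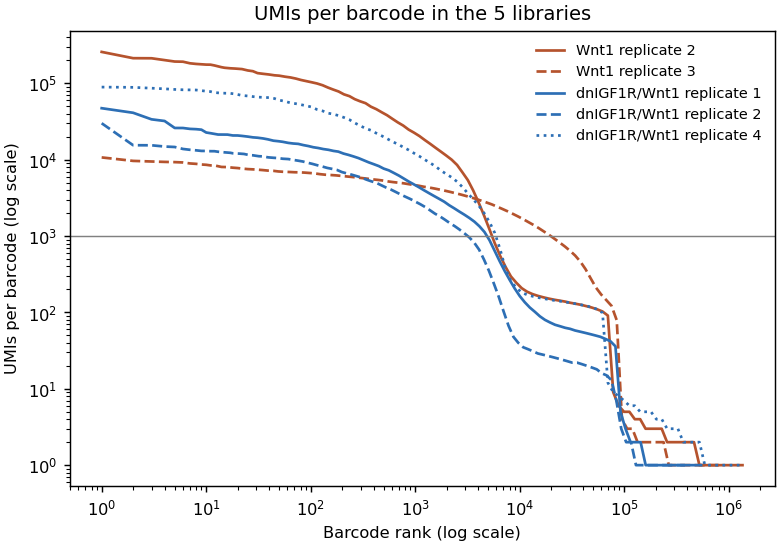
UMIs per barcode (log axis) against barcode rank (log axis), 1 line per library, colored by genotype. Wnt1 replicate 3 held 36454 barcodes with at least 500 UMIs and the other 4 libraries held between 4539 and 6868.

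Epithelial-like cells were the most abundant class in each library. They made up 59.1% ± 13.7 (SD, n = 2) of Wnt1 and 46.6% ± 2.14 (SD, n = 3) of dnIGF1R/Wnt1 cells. Macrophage-like cells were 9.57% ± 1.315 and 11.8% ± 2.03 and fibroblast-like cells 6.04% ± 0.346 and 3.78% ± 2.01. Endothelial-like cells were 4.08% ± 0.665 of Wnt1 and 1.72% ± 0.710 of dnIGF1R/Wnt1 cells, lower in each of the 3 dnIGF1R/Wnt1 libraries than in both Wnt1 libraries (edgeR log2 -1.24 ± 0.45 (SE), adjusted p = 0.286, exact permutation p = 0.2). Luminal-like cells were also separated, with 27.9% ± 4.60 against 19.2% ± 1.77 (log2 -0.54, adjusted p = 0.443, exact permutation p = 0.2), whereas basal-like cells were 4.47% ± 3.66 and 2.92% ± 0.871 (exact permutation p = 0.8). These are shares of all kept cells, and clusters abundant in some libraries lower the others. With an unnamed epithelial cluster led by Acta1 and neutrophil-like cells out of the total, luminal-like cells overlapped between the groups, at 28.55% ± 5.16 and 26.8% ± 2.90 (exact permutation p = 0.6), and with the mixed clusters also out, 27.4% of Wnt1 replicate 3, they were separated again, at 33.55% ± 1.34 and 27.5% ± 3.01 (0.2). With both totals endothelial-like cells were separated, at 4.185% ± 0.742 and 2.36% ± 0.786 and then at 4.915% ± 0.219 and 2.42% ± 0.805, and so were macrophage-like cells, at 9.835% ± 1.51 and 16.4% ± 2.65 and then at 11.55% ± 0.778 and 16.9% ± 2.75 (0.2 each). The latter overlapped at 16.1% ± 6.08 and 17.9% ± 3.25 once a mixed cluster with macrophage genes, 11.4% of Wnt1 replicate 3, was counted with them (0.6). With the Acta1-led cluster counted as epithelial, the epithelial share was 61.4% ± 14.99 and 68.9% ± 14.02 of all cells (0.4), and 71.35% ± 2.05 and 70.2% ± 14.04 of cells outside the mixed clusters (exact permutation p = 1). Pericyte-like cells took 2.58 and 2.49%, and epithelial cells without a named lineage 26.8 and 24.5%.

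Some clusters were unevenly spread over the libraries. Neutrophil-like cells were 17.2% of dnIGF1R/Wnt1 replicate 4 and at most 0.179% of each other library, with 0 of 4722 and 0 of 3026 cells in dnIGF1R/Wnt1 replicates 1 and 2, which allows up to 0.0781 and 0.122% (exact 95% limits). A mixed cluster with neutrophil genes took a further 6.8% of Wnt1 replicate 3 and 1.1% of dnIGF1R/Wnt1 replicate 4. T cell-like cells were 2.79% of the same replicate 4, 0.106 and 0.0330% of dnIGF1R/Wnt1 replicates 1 and 2, and 0.818 and 1.08% of the Wnt1 libraries. An unnamed cluster with macrophage and dendritic cell markers, led by Retnla, Ccl5 and H2-Aa, was 6.11% of replicate 4 and between 0.462 and 1.64% of the other libraries. The cluster led by Acta1, a skeletal muscle gene, Gal and Mia held 36.2, 26.2 and 4.65% of dnIGF1R/Wnt1 replicates 1, 2 and 4 and 3.27 and 1.38% of the Wnt1 libraries (edgeR log2 3.27 ± 1.16 (SE), adjusted p = 0.286, exact permutation p = 0.2). Over 7 clusterings, endothelial-like shares of all cells were separated in 7, luminal-like in 5, this cluster in 3 and macrophage-like in 0, and this cluster took 15.1% of Wnt1 replicate 3 at resolution 0.5. No class passed the edgeR test of shares (0 of 12). Without Wnt1 replicate 2 the count was 1, and without dnIGF1R/Wnt1 replicate 4 it was 2, with the share of T cell-like cells at log2 -3.66 (adjusted p = 0.0203). An 8-fold simulated change was called in 2% of simulations with a common dispersion and in 91% with each class's own, beside 0.01 and 0.72 other classes called per simulation.

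**Figure D2:**
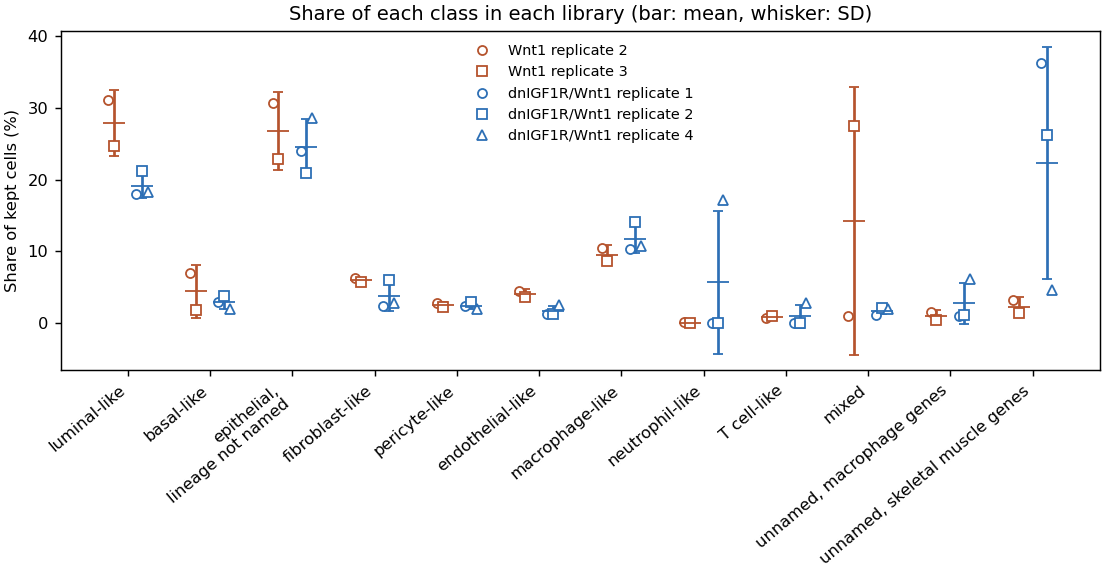
Percent of kept cells per class, with 1 point per library and bars at the group mean with whiskers of 1 SD (n = 2 Wnt1, n = 3 dnIGF1R/Wnt1), some of which reach below 0. Endothelial-like cells averaged 4.08% in Wnt1 and 1.72% in dnIGF1R/Wnt1, and neutrophil-like cells reached 17.2% in a single library.

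Wnt1 (ENSMUSG00000022997, chromosome 15, 98789857 to 98793837 of mm10) was present in all 5 libraries, at 66.4 and 68.1 CPM of whole tumor in Wnt1 and at 52.2, 66.1 and 32.3 CPM in dnIGF1R/Wnt1 replicates 1, 2 and 4 (log2 -0.43 ± 0.29 (SE), adjusted p = 0.66). Igf1r (ENSMUSG00000005533, chromosome 7, 67952827 to 68233668) was at 119.7 and 133.2 against 105.2, 126 and 137.9 CPM (log2 -0.04 ± 0.18, adjusted p = 0.96). This reads the mouse gene and checks nothing on the transgene if that does not align to the mouse reference. Insr, the insulin receptor, was at 46.0 and 43.1 against 29.9, 34.9 and 41.5 CPM (log2 -0.33 ± 0.18, adjusted p = 0.612). By class, Wnt1 separated the groups in basal-like cells, at 41.2 and 22.5 CPM (log2 -1.01, adjusted p = 0.808), endothelial-like cells (-1.16, 1) and lineage-not-named cells (-0.43, 0.649), Igf1r in basal-like (-0.24, 0.924) and macrophage-like cells (-0.44, 0.902), and Insr in macrophage-like cells (-0.58, 0.902).

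In epithelial-like cells the gene with the smallest p was Rnaset2a, which encodes a lysosomal ribonuclease (ENSMUSG00000095687, chromosome 17, 8115445 to 8148097). It was at 25.95 ± 6.88 CPM (SD, n = 2) in Wnt1 and 103.0 ± 7.33 CPM (SD, n = 3) in dnIGF1R/Wnt1, a 3.98-fold difference (log2 1.99 ± 0.21 (SE), adjusted p = 0.287). Mthfsl was at 11.98 and 29.5 CPM (log2 1.29 ± 0.19), and Grm8, a glutamate receptor gene, at 1.34 and 5.59 CPM (log2 2.05 ± 0.31). On the lower side, Ism2 was at 2.60 and 0.307 CPM (log2 -3.09 ± 0.50), Nrbp2 at 28.4 and 15.1 CPM (log2 -0.90 ± 0.17), and Cmss1 at 286.5 and 137.4 CPM (log2 -1.06 ± 0.20). All 6 separated the libraries of the groups and were called by DESeq2, with adjusted p from 1.61e-13 for Rnaset2a to 0.0139 for Nrbp2, though DESeq2 called 56 unchanged genes in the simulation of this class. Cdh3, which encodes P-cadherin, was at 46.6 ± 3.90 and 63.4 ± 13.6 CPM (log2 0.45 ± 0.21, adjusted p = 0.633), and separated in whole tumor (0.57, 0.538) and pericyte-like cells, at 28.8 and 58.3 CPM (1.004, 0.494). Cdh1, E-cadherin, was at 151.3 ± 34.7 and 142.0 ± 14.9 CPM (log2 -0.09 ± 0.20, adjusted p = 0.918). Of 16053 genes, 0 passed the edgeR test, 1288 had an unadjusted p under 0.05 (718 higher, 570 lower), and DESeq2 called 145 (124 higher, 21 lower) and gave no adjusted p for 1875. The edgeR count became 305 without Wnt1 replicate 2 and 296 without Wnt1 replicate 3, in fits where the lone Wnt1 library was assumed to vary like the other group. With library size only in place of TMM the median log2 difference of all genes moved from -0.04 to -0.19.

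Genes of energy metabolism were higher as groups in dnIGF1R/Wnt1 epithelial-like cells. Of the glycolysis and hypoxia genes, 15 of 17 were higher, with a median log2 of 0.45 (camera adjusted p = 1.59e-05; adjusted p = 0.87 with an estimated correlation). Among them Pgk1, Gapdh and Aldoa, enzymes of glycolysis, were higher by log2 0.71, 0.82 and 0.77, and Vegfa by 0.64. Of the oxidative phosphorylation genes, 13 of 17 were higher, with a median of 0.46 (camera adjusted p = 6.1e-05; adjusted p = 0.443 with an estimated correlation), among them Cycs, which encodes cytochrome c, at 0.80 and the respiratory chain genes Ndufa4, Cox5a and Ndufb8 at 0.69, 0.64 and 0.57. Both calls held in all 16 alternatives run with the preset correlation. Of the oxidative stress genes, 13 of 18 were higher, with a median of 0.23 and the glutathione transferase gene Gstp1 at 1.46 (camera adjusted p = 0.0193; adjusted p = 0.87 with an estimated correlation), a call lost without Wnt1 replicate 3 (adjusted p = 0.215), dnIGF1R/Wnt1 replicate 2 (0.0612) and dnIGF1R/Wnt1 replicate 4 (0.0505). In every tested class 0 members of the lists passed over all genes. Adjusted over the list alone, 0, 0 and 1 members of these 3 lists did, the last being Gstp1.

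Milk and cell cycle genes were also called in epithelial-like cells, with less hold. Of the alveolar luminal and milk genes, 11 of 15 were higher, with a median log2 of 0.63 and the casein genes Csn2 and Csn1s1 at 5.33 ± 2.10 (SE) and 2.95 (camera adjusted p = 0.0193). Of the proliferation genes, 16 of 27 were higher, with a median of 0.165, Ube2c at 1.03 and Birc5 at 0.70 (camera adjusted p = 0.0265; adjusted p = 0.87 with an estimated correlation for both). Of each list 0 members passed over the list alone. The class mixes makeup with expression: its cluster led by Hist1h1b, Hist1h2ap and Ube2c held 1.45 and 8.62% of its cells in the Wnt1 and 15.7, 15.4 and 3.8% in the dnIGF1R/Wnt1 libraries. The milk call held in 7 of 16 alternatives and turned the other way without Wnt1 replicate 2 (adjusted p = 0.723), and it was lost without dnIGF1R/Wnt1 replicate 4 (0.053). The proliferation call held in 5 of 16, and it was lost without Wnt1 replicate 2 (0.969) and without dnIGF1R/Wnt1 replicates 1 (0.27) and 2 (0.433). With clustering seeds 1 and 2 both calls were lost (0.172 and 0.051 for milk genes, 0.319 and 0.0738 for proliferation).

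The lists closest to the transgenes gave no call by camera in epithelial-like cells. IGF axis genes had a median log2 of 0.18 with 10 of 15 higher (camera adjusted p = 0.211; 0.858 by directional and 0.0397 by mixed fry), with the binding protein Igfbp3 at 0.62, the receptor adaptor Grb14 at 0.56 and the insulin receptor substrate Irs2 at -0.32. Wnt target genes had a median of 0.07 (adjusted p = 0.478), with the Wnt inhibitor Wif1 at 0.72, Ccnd1, which encodes cyclin D1, at -0.56, and Axin2 at -0.38. FOXO target genes had a median of -0.07 (adjusted p = 0.417), ER stress genes -0.20 with 14 of 19 lower (0.478), and amino acid stress genes 0.05 (0.383). Igf1 itself was near the detection floor in these cells, at 0.727 and 0.23 CPM.

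Other lineage and surface programs were not called in epithelial-like cells. Hormone-sensing luminal genes had a median log2 of 1.22 (camera adjusted p = 0.0912), with Esr1, the estrogen receptor, at 1.23 and Areg at 3.25, and epithelial adhesion genes had a median of -0.09 (0.484). Basal lineage genes had a median of 0.11, mesenchymal genes -0.26, proteases and inhibitors -0.16, angiogenesis genes -0.23, fibroblast activation genes 0.39, cholesterol synthesis genes -0.13, dissociation stress genes 0.11 and apoptosis and p53 genes 0.05, each with an adjusted p of 0.478. Matrix proteins had a median of -0.30 (adjusted p = 0.478), with 1 member, Col6a3, a chain of collagen VI, passing upward at 1.225 when adjusted over the list alone. MHC class I genes had a median of 0.28 (0.072), MHC class II genes -0.93 (0.558), and interferon genes 0.56 (0.81). Cytokines had a median of -0.14 (0.824). Except for Col6a3 and Gstp1, 0 members of all lists here passed adjusted over the list alone.

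**Figure D3:**
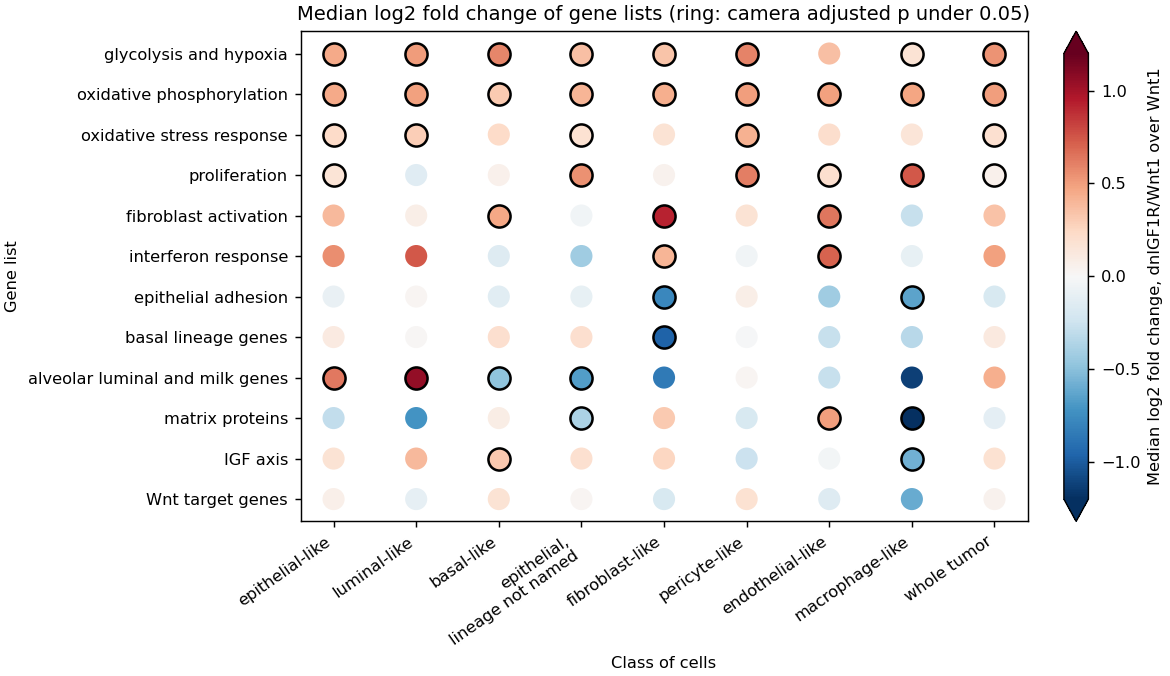
Median log2 difference (color; dnIGF1R/Wnt1 over Wnt1) of 12 gene lists in each tested class, with rings where the camera adjusted p with the preset correlation was under 0.05. Oxidative phosphorylation was ringed in all 9 partly overlapping classes, and no ring held with an estimated correlation.

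Luminal-like cells of dnIGF1R/Wnt1 tumors were higher in milk and hormone-sensing genes. Of the alveolar luminal and milk genes, 12 of 15 were higher, with a median log2 of 1.05 (camera adjusted p = 2.77e-06; adjusted p = 0.8 with an estimated correlation), among them the casein gene Csn3 at 1.05, Wfdc18 at 1.07, the transferrin gene Trf at 1.09, and Spp1, osteopontin, at 2.72. Of the hormone-sensing genes, 10 of 11 were higher, with a median of 1.797 (camera adjusted p = 0.00757; adjusted p = 0.998 with an estimated correlation), with Esr1 at 1.797 and Areg at 3.64. Adjusted over the list alone 0 members of either list passed. The cluster led by Csn3 held 28 and 55.6% of luminal-like cells in the Wnt1 and 43.4, 44.6 and 29.3% in the dnIGF1R/Wnt1 libraries, and the one led by Sprr1a 39.3 and 4.7% and 14.6, 14.6 and 11.4%, so makeup enters these values. A cluster led by Prlr and Areg held 1.67 and 1.66% of these cells in the Wnt1 and 1.88, 3.73 and 26.1% in the dnIGF1R/Wnt1 libraries. Without dnIGF1R/Wnt1 replicate 4 the hormone-sensing call was lost (adjusted p = 0.5), as it was without Wnt1 replicate 2 or 3. The milk call was lost without Wnt1 replicate 2 (adjusted p = 0.373).

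Metabolic genes were higher in luminal-like cells as well. Oxidative phosphorylation genes had a median log2 of 0.49 with 13 of 17 higher (camera adjusted p = 2.77e-06), glycolysis genes 0.51 with 16 of 17 higher (7.27e-05), and oxidative stress genes 12 of 18 higher (3.7e-04; adjusted p = 0.314, 0.934 and 0.542 in turn with an estimated correlation). Of the called lists of all classes, directional fry gave only oxidative phosphorylation in this class an adjusted p under 0.05 (0.0342; 0.177 to 0.999 for the others), and mixed fry only oxidative stress here (0.0375) and in epithelial-like cells (0.0397). Dissociation stress genes, among them Zfp36, Btg2 and the heat shock gene Hspa1a, were higher too (0.0272; adjusted p = 0.998 with an estimated correlation). Members that passed adjusted over the list alone were 1 for oxidative phosphorylation, 1 for oxidative stress and 0 for the other lists. Glycolysis lost its call without Wnt1 replicate 2 (adjusted p = 0.0686) and oxidative stress without Wnt1 replicate 3 (0.0765), while dissociation stress lost it without dnIGF1R/Wnt1 replicate 1 (0.0658), turned the other way without Wnt1 replicate 3 (0.383) and held in 11 of 15 alternatives.

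Among single genes of luminal-like cells, Rnaset2a was at 24.6 and 104.3 CPM (log2 2.085 ± 0.19 (SE), adjusted p = 0.0665), Mthfsl at 13.8 and 39.1 CPM (log2 1.48 ± 0.22) and Gstp1 at 26.01 and 68.2 CPM (log2 1.38 ± 0.21). The calcium-binding protein gene S100b was at 36.1 and 18.8 CPM (log2 -0.96), the anion transporter gene Slco2b1 at 2.88 and 0.484 CPM (log2 -2.82), and Cmss1 at 330.5 and 170.2 CPM (log2 -0.96). Of 14226 genes, 0 passed the edgeR test, 948 had an unadjusted p under 0.05 (655 higher, 293 lower), and DESeq2 called 114 (108 higher, 6 lower) but gave no adjusted p for 13238, Rnaset2a among them. The edgeR count was 477 without Wnt1 replicate 2 and 178 without Wnt1 replicate 3.

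Basal-like cells held the single gene that passed the edgeR test of genotype within a class. Rnaset2a rose from 21.6 ± 3.50 CPM (SD, n = 2) to 89.8 ± 4.21 CPM (SD, n = 3), higher in all 3 dnIGF1R/Wnt1 libraries than in both Wnt1 libraries (log2 2.10 ± 0.26 (SE), adjusted p = 0.0285). Of 8560 genes, edgeR called 1, 506 had an unadjusted p under 0.05 (245 higher, 261 lower), and DESeq2 called 5, all higher. The call of Rnaset2a did not hold without dnIGF1R/Wnt1 replicate 1 (adjusted p = 0.512), 2 (0.565) or 4 (0.338) or with the looser cell filter (0.101). The edgeR count was 228 without Wnt1 replicate 2, 386 without Wnt1 replicate 3 and 0 without each dnIGF1R/Wnt1 library.

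As lists, glycolysis genes, genes of the IGF axis and milk genes differed in basal-like cells. Glycolysis and hypoxia genes were higher in 12 of 14 members, with a median log2 of 0.58, Pgk1 at 0.90 and the glucose transporter gene Slc2a1 at 0.97, and the call held in all 15 alternatives (camera adjusted p = 2.47e-04). IGF axis genes were higher in 8 of 12 members, with a median of 0.325 (0.0118; adjusted p = 0.586 with an estimated correlation for both). Those with the smallest p were the binding proteins Igfbp3 at 1.18, Igfbp7 at 0.84 and Igfbp2 at 1.06 and the receptor gene Igf2r at 0.75, while Igf1r was at -0.24 and Insr at 0.07. Alveolar luminal and milk genes were lower in 8 of 10 members, with Csn3 and Mfge8 falling adjusted over the list alone at -2.50 and -1.24 (0.0118; adjusted p = 0.589 with an estimated correlation). The luminal genes Krt8 and Cldn7 were lower beside them, at 88.1 and 27.5 CPM and at 115.3 and 38.6 CPM (adjusted p = 0.27 for both), and the upper estimate of free RNA in basal-like cells was 20.4% in Wnt1 replicate 3, 4.51% in Wnt1 replicate 2 and 3.95 to 9% in dnIGF1R/Wnt1. Oxidative phosphorylation genes had a median of 0.31 with 13 of 17 higher (0.0118), fibroblast activation genes had 6 of 7 higher with the chemokine gene Cxcl1 at 2.59 (0.0267), and ER stress genes had 14 of 18 lower with the chaperone gene Calr at -0.54 (0.0343; adjusted p = 0.586 with an estimated correlation for each). Adjusted over the list alone, 0 members of these lists other than the milk genes passed. Without Wnt1 replicate 2 the adjusted p was 0.325 for the IGF axis, 0.585 for fibroblast activation and 0.215 for ER stress and oxidative phosphorylation. Without Wnt1 replicate 3 it was 0.442 for milk genes and 0.0514 for ER stress. Without dnIGF1R/Wnt1 replicate 1 it was 0.0573, 0.0794, 0.212 and 0.113 for the IGF axis, milk, fibroblast activation and ER stress. It was 0.191 for ER stress without replicate 2 and 0.226 for fibroblast activation without replicate 4. Of the 15 alternatives, the IGF axis call held in 7, ER stress in 7, milk genes in 9 and fibroblast activation in 6. With clustering seeds 1 and 2 the IGF axis was at 0.0681 and 0.233.

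**Figure D4:**
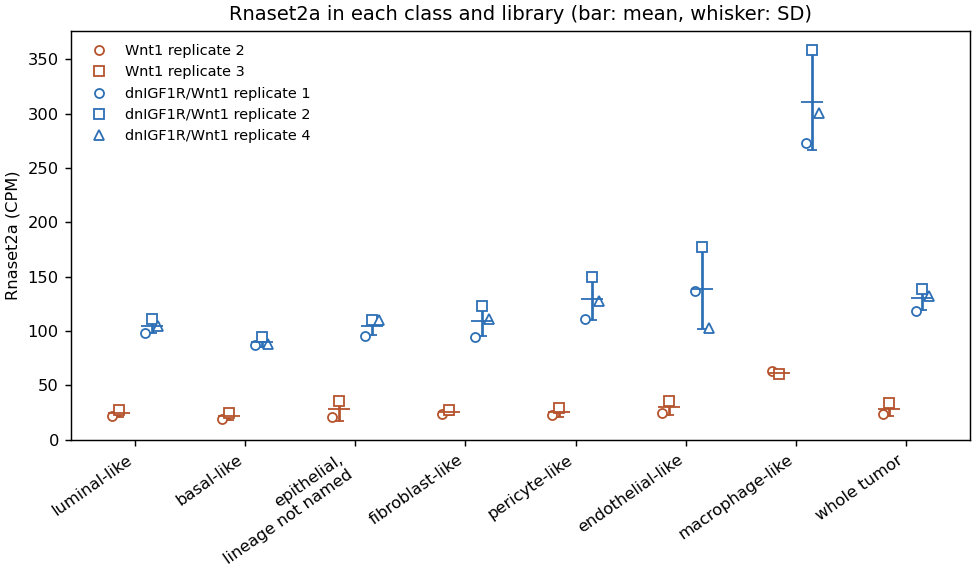
Rnaset2a in CPM per class, with 1 point per library, bars at the group means and whiskers of 1 SD (n = 2 Wnt1, n = 3 dnIGF1R/Wnt1). Basal-like means were 21.6 and 89.8 CPM and macrophage-like means 61.5 and 310.5 CPM, and all dnIGF1R/Wnt1 libraries lay above all Wnt1 libraries in each class shown.

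The genotype difference was not the same in basal-like and luminal-like cells for 44 of 12760 genes by the interaction test, and in 39 of them the log2 difference was higher in luminal-like cells. Csn3, a casein gene, was at 314.4 and 648.6 CPM in luminal-like and at 40.9 and 5.875 CPM in basal-like cells of Wnt1 and dnIGF1R/Wnt1 (log2 basal minus luminal -3.75 ± 0.36 (SE), adjusted p = 2.23e-05). Areg, an EGF receptor ligand, was at 16.4 and 203.1 CPM in luminal-like cells and had too few counts in basal-like cells to be tested there alone (-3.53 ± 0.55, adjusted p = 2.49e-04). At an unadjusted p under 0.05 there were 924 genes, and DESeq2 called 5, with Csn3 at an adjusted p of 0.506. The 5, looked up after the result was seen and also called by edgeR, were the luminal keratin genes Krt8 and Krt18, the claudin gene Cldn7, Trf and Hp. Krt8 was at 106.5 and 69.7 CPM in basal-like cells of Wnt1 replicates 2 and 3. In 10 simulations without any effect, between 4 and 18 genes were called with each gene's own dispersion and 0 with the trended dispersion. The count was 27 without Wnt1 replicate 2, 172 without Wnt1 replicate 3, and 23, 42 and 13 without dnIGF1R/Wnt1 replicates 1, 2 and 4. It was 34 and 56 with clustering seeds 1 and 2. For Csn3, basal-like against luminal-like, the call held without each library in turn and was lost in other clusterings, at resolution 0.5 (adjusted p = 0.279) and with the 3 marked doublets kept (0.865). For Areg, basal-like against luminal-like, the difference was 2.405 without Wnt1 replicate 2 (adjusted p = 0.974) and lost its call without dnIGF1R/Wnt1 replicate 4 (0.72).

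Fibroblast-like cells of dnIGF1R/Wnt1 tumors were higher in genes of activated fibroblasts. Of the fibroblast activation genes, 12 of 13 were higher, with a median log2 of 0.92 (camera adjusted p = 6.81e-07; adjusted p = 0.543 with an estimated correlation), and 6 passed adjusted over the list alone against 0 over all genes. Cthrc1, a secreted matrix protein, was higher by log2 1.83, and the contractile genes Acta2 and Tagln by 1.27 and 1.375, and the call held in all 15 alternatives. Acta2 was also among the leading genes of the pericyte-like cluster with doublets kept. Cytokines and chemokines were higher in 16 of 20 members, with Ccl2, which attracts monocytes, at 2.23 (0.00121). Interferon genes were also higher, with Isg15 at 1.53, Bst2 at 1.501 and Ifi27l2a at 1.42 (0.00315), as were proteases and inhibitors, with Timp1 at 1.74 and Plaur at 1.297 (0.00393; adjusted p = 0.543 with an estimated correlation for each of these lists). Adjusted over the list alone, 1 cytokine gene, 3 interferon genes and 2 genes of the protease list passed. The cytokine and protease calls were lost without Wnt1 replicate 2 (adjusted p = 0.638 and 0.102), and the cytokine, interferon and protease calls without dnIGF1R/Wnt1 replicate 4 (0.119, 0.0827 and 0.0656). They held in 9, 9 and 7 of 15 alternatives. With clustering seed 2, which kept 242 of the 1847 cells in this class, they were at 0.106, 0.134 and 0.289.

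Epithelial genes were lower in the same fibroblast-like cells. Epithelial adhesion genes were lower in 14 of 15 members, with a median log2 of -0.78 and the desmosome gene Dsp at -1.88, and 1 member passed adjusted over the list alone (camera adjusted p = 6.55e-04). Basal lineage genes were lower as a list, with the keratin gene Krt14 at -1.60 and Col17a1 at -2.17, with 3 members rising and 5 falling adjusted over the list alone (0.015; adjusted p = 0.543 with an estimated correlation for both). The upper estimate of free RNA in fibroblast-like cells of Wnt1 replicate 3 was 50.6% of their UMIs, and without that library the adhesion call (adjusted p = 0.594) and the basal call (0.0881) were lost, the latter also without dnIGF1R/Wnt1 replicate 4 (0.25). The adhesion list turned the other way with the looser cell filter (0.947), with doublets kept (0.78) and with clustering seed 2 (0.787), and the basal list with free-RNA genes left out (0.0362) and with doublets removed at a fixed rate (0.684).

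Among single genes of fibroblast-like cells, Rnaset2a was at 25.1 and 109.5 CPM (log2 2.13 ± 0.32 (SE), adjusted p = 0.144), the interferon-inducible Ifi211 at 18.2 and 65.6 CPM (log2 1.86) and the protease inhibitor gene Tfpi2 at 12.4 and 49.7 CPM (log2 1.98). Gt(ROSA)26Sor was at 21.96 and 1.92 CPM (log2 -3.80). The keratin gene Krt79 and Ctnna3, which led an epithelial cluster, were at 66.2 and 20.5 (-1.57) and 84.5 and 29.6 CPM (-1.44). Free RNA may enter both. Further lists called by camera were glycolysis upward (2.91e-04), oxidative phosphorylation upward (0.00315; adjusted p = 0.567 with an estimated correlation), MHC class II downward (0.00315) and mesenchymal genes upward (0.0236). Glycolysis, MHC class II and mesenchymal genes had an adjusted p = 0.543 with an estimated correlation. Adjusted over the list alone 1 mesenchymal gene and 0 members of the others passed. Of 10138 genes, 0 passed the edgeR test, 578 had an unadjusted p under 0.05 (331 higher, 247 lower), and DESeq2 called 17 (15 higher, 2 lower) and gave no adjusted p for 4720. The edgeR count was 412 without Wnt1 replicate 2 and 203 without Wnt1 replicate 3. Glycolysis and oxidative phosphorylation lost their calls without Wnt1 replicate 2 (adjusted p = 0.24 and 0.321). The mesenchymal and MHC class II calls were lost without Wnt1 replicate 3 (0.594 and 0.453) and the mesenchymal call also without dnIGF1R/Wnt1 replicates 1 and 4 (0.086 and 0.119). Glycolysis and oxidative phosphorylation held in 11 of 15 alternatives each and mesenchymal genes in 6.

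Macrophage-like cells of dnIGF1R/Wnt1 tumors were higher in genes of the cell cycle. Of the proliferation genes, 26 of 27 were higher, with a median log2 of 0.745 (camera adjusted p = 2.85e-15; adjusted p = 0.715 with an estimated correlation), and 4 passed adjusted over the list alone against 0 over all genes. Among them Birc5 was at 1.56 and the mitotic kinase gene Cdk1 at 1.504, and the call held in all 15 alternatives. IGF axis genes were lower in 11 of 12 members, with a median of -0.57 (0.0246; adjusted p = 0.905 with an estimated correlation), among them Igfbp7 at -0.98, Insr at -0.58, Irs2 at -0.56 and Igf1r at -0.44. FOXO target genes were lower in 13 of 16 members, with Sesn3 at -0.89 (0.007; adjusted p = 0.715 with an estimated correlation). Matrix genes were lower, with Col1a1 at -2.06 (5.85e-06), as were epithelial adhesion genes (0.007; adjusted p = 0.905 with an estimated correlation for both) and mesenchymal genes (0.0144; adjusted p = 0.715 with an estimated correlation), beside an upper estimate of free RNA of 34.4% in macrophage-like cells of Wnt1 replicate 3. Without that library the matrix and adhesion lists turned the other way (adjusted p = 0.287 and 0.0895), and the mesenchymal (0.231), IGF axis (0.349) and FOXO calls (0.0605) were lost. The adjusted p was 0.0561 for the IGF axis and 0.159 for FOXO target genes without Wnt1 replicate 2, and the IGF axis also lost its call without dnIGF1R/Wnt1 replicate 1 (0.195) and held in 7 of 15 alternatives.

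In macrophage-like cells Rnaset2a was at 61.5 and 310.5 CPM (log2 2.33 ± 0.29 (SE), adjusted p = 0.385), the dynein light chain gene Dynlt1f at 12.4 and 48.9 CPM (log2 1.99) and Mthfsl at 20.4 and 70.6 CPM (log2 1.77). Glipr2 was at 18.4 and 3.99 CPM (log2 -2.15), F10, the gene of coagulation factor X, at 51.8 and 12.3 CPM (log2 -2.01), and Krt14, an epithelial keratin gene, at 81.04 and 28.7 CPM (log2 -1.55). Oxidative phosphorylation (5.85e-06; adjusted p = 0.715 with an estimated correlation) and glycolysis (0.0475) were called upward by camera, and cholesterol synthesis downward (0.0374; adjusted p = 0.905 with an estimated correlation for the last 2), and beyond proliferation 0 members of the called lists passed adjusted over the list alone. Of 11159 genes, 0 passed the edgeR test, 579 had an unadjusted p under 0.05 (367 higher, 212 lower), and DESeq2 called 14 (10 higher, 4 lower) and gave no adjusted p for 5628. Leave-out counts by edgeR were 1442 without Wnt1 replicate 2 and 416 without Wnt1 replicate 3, with 44 genes in both in the same direction, against 53.8 for independent lists. Glycolysis held in 9 of 15 alternatives. It turned the other way without Wnt1 replicate 2 (adjusted p = 0.779) and lost its call without dnIGF1R/Wnt1 replicate 2 (0.499) and with the length trend removed (0.0582), and cholesterol synthesis lost its call without Wnt1 replicate 3 (0.596) and dnIGF1R/Wnt1 replicates 1 (0.123) and 4 (0.0525).

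In endothelial-like cells Sox18, a transcription factor of vessels, was at 41.4 and 165.2 CPM (log2 1.993 ± 0.442 (SE)), Ost4, a subunit of the enzyme that attaches sugar chains to proteins, at 108.0 and 342.6 CPM (log2 1.66 ± 0.37), and Rnaset2a at 29.97 and 138.9 CPM (log2 2.15 ± 0.39, adjusted p = 0.63). Sele, the adhesion molecule E-selectin, was at 136.0 and 34.8 CPM (log2 -1.67 ± 0.40). The kinase gene Camk1d, lower in each class that shares no cells, was at 558.0 and 158.4 CPM (log2 -1.73). The histone gene Hist1h2be was at 18.2 and 1.89 CPM (log2 -3.41). Fibroblast activation genes were higher as a list, with Tagln at 1.54 and Acta2 at 1.51 (camera adjusted p = 0.00141; adjusted p = 0.714 with an estimated correlation), as were oxidative phosphorylation genes (0.00141; adjusted p = 0.914 with an estimated correlation). Matrix genes were higher too, with Col6a3 at 1.36 (0.0018; adjusted p = 0.959 with an estimated correlation), and so were proliferation and MHC class I genes (0.0231 each) and interferon genes, with Bst2 at 1.395 (0.049; adjusted p = 0.959 with an estimated correlation for each). The upper estimate of free RNA in these cells was 12.2 and 67.6% in Wnt1 replicates 2 and 3 and 21.09, 12.51 and 37.75% in dnIGF1R/Wnt1 replicates 1, 2 and 4. Adjusted over the list alone, 1 fibroblast activation gene, 1 matrix gene and 0 members of the other called lists passed. Of 9810 genes, 0 passed the edgeR test, 258 had an unadjusted p under 0.05 (182 higher, 76 lower), and DESeq2 called 0. The edgeR count was 181 without Wnt1 replicate 2 and 137 without Wnt1 replicate 3. Calls were lost without Wnt1 replicate 2 for oxidative phosphorylation (adjusted p = 0.23) and, with the other sign, proliferation (0.935), and without Wnt1 replicate 3 for matrix (0.0672) and MHC class I (0.0804). They were also lost without dnIGF1R/Wnt1 replicate 4 for matrix (0.846), MHC class I (0.152) and, with the other sign, interferon genes (0.971), without dnIGF1R/Wnt1 replicate 2 for proliferation (0.416), MHC class I (0.0527) and interferon genes (0.111), and without dnIGF1R/Wnt1 replicate 1 for proliferation (0.291). Proliferation, MHC class I and interferon genes held in 9, 9 and 8 of 15 alternatives, and with the length trend removed all 3 lost their calls (0.0734, 0.188 and 0.229).

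Genes of T cell-like cells were not tested, since the rule asked for 2 libraries per group with at least 20 such cells, and 2 Wnt1 libraries and 1 dnIGF1R/Wnt1 library held them. In whole tumor, where the list could be measured, T cell cytotoxicity genes were higher in 9 of 10 members, with a median log2 of 0.41 (camera adjusted p = 0.884), while fry pointed downward (adjusted p = 0.998) and T cell-like cells were most frequent in dnIGF1R/Wnt1 replicate 4 and rarest in replicates 1 and 2.

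Summed over all cells, which mixes makeup with expression, dnIGF1R/Wnt1 tumors were lower in genes of endothelial activation. The angiogenesis list was lower in 9 of 13 members, with a median log2 of -0.76 and with Sele at -2.33, the VEGF receptor gene Kdr at -1.34 and Vwf at -1.12 (camera adjusted p = 8.74e-04; adjusted p = 0.96 with an estimated correlation), beside the lower share of endothelial-like cells, and 1 member passed adjusted over the list alone. Within endothelial-like cells the list was not called (median -0.18, 10 of 13 lower, camera adjusted p = 0.221), and adjusted over the list alone 2 members rose and 1 fell. Glycolysis and hypoxia genes were higher in 16 of 17 members (4.56e-07; adjusted p = 0.903 with an estimated correlation), 2 of them adjusted over the list alone, and oxidative phosphorylation genes in 14 of 17 (1.48e-05; adjusted p = 0.387 with an estimated correlation). Proliferation (0.0186), oxidative stress (0.0293) and MHC class I genes (0.0293) were called upward (adjusted p = 0.96 with an estimated correlation for each), with 0, 1 and 0 members passing adjusted over the list alone. Rnaset2a was at 28.6 and 129.9 CPM (log2 2.19 ± 0.21 (SE), adjusted p = 0.474), Mthfsl at 12.3 and 32.5 CPM (log2 1.398) and the Mediator subunit gene Med30 at 25.2 and 54.1 CPM (log2 1.10), while Clmn was at 50.8 and 26.7 CPM (log2 -0.93), Shank2 at 35.5 and 17.7 CPM (log2 -1.01) and Klhdc7a at 14.99 and 6.61 CPM (log2 -1.18). Of 18053 genes, 0 passed the edgeR test, 1616 had an unadjusted p under 0.05 (813 higher, 803 lower), and DESeq2 called 260 (207 higher, 53 lower) and gave no adjusted p for 3197. Without Wnt1 replicate 2 the adjusted p was 0.0506 for angiogenesis, 0.981 for proliferation, 0.0506 for oxidative stress and 0.243 for MHC class I. Oxidative stress and MHC class I also lost their calls without Wnt1 replicate 3 (0.399 and 0.179) and dnIGF1R/Wnt1 replicate 4 (0.0539 and 0.642), and proliferation without dnIGF1R/Wnt1 replicates 1 and 2 (0.068 and 0.245).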

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

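The test of the difference between basal-like and luminal-like cells was chosen before the data were examined, while the rule for naming its genes, the clustering seeds and the library shares set beside it were chosen after its result was seen. The genotype difference was unequal in these classes for 44 genes, of which 10 are given here as the log2 difference in basal-like minus that in luminal-like cells, by edgeR. Csn3 was at -3.748 (adjusted p = 2.23e-05), Areg at -3.532 (2.49e-04) and Cdo1, which encodes cysteine dioxygenase, at -2.98 (0.0183). Lypd3 was at -8.506 (0.0431) and AW112010 at -4.658 (0.0431), with 8.926 and 101.6 CPM in luminal-like cells of Wnt1 and dnIGF1R/Wnt1. Areg, Cdo1, Lypd3 and AW112010 had too few counts in basal-like cells to be tested there alone. In the other 5 the log2 difference was higher in basal-like cells: Cldn11, a tight junction gene, at 2.077 (0.0332), Hmcn1 at 1.07 (0.0213), Pde7b at 1.059 (0.00819), Cd44 at 0.856 (0.041) and the adhesion gene Cadm1 at 0.74 (0.0367).

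Single libraries and the clustering weighed on these values. Without dnIGF1R/Wnt1 replicate 4 the adjusted p was 1.29e-06 for Csn3, basal-like against luminal-like, 0.72 for Areg, basal-like against luminal-like, 0.306 for Cdo1, basal-like against luminal-like, 0.359 for Lypd3, basal-like against luminal-like, 0.919 for AW112010, basal-like against luminal-like, 0.306 for Cldn11, basal-like against luminal-like, 0.722 for Hmcn1, basal-like against luminal-like, 0.414 for Pde7b, basal-like against luminal-like, 0.619 for Cd44, basal-like against luminal-like, and 0.306 for Cadm1, basal-like against luminal-like. Without Wnt1 replicate 2 Csn3 (8.78e-06) and AW112010 (6.33e-04) held, Areg turned to 2.405 (0.974), and Cdo1 (0.255), Lypd3 (0.223), Cldn11 (0.931), Hmcn1 (0.0993), Pde7b (0.288), Cd44 (0.661) and Cadm1 (0.4) lost their calls. Without Wnt1 replicate 3 AW112010 lost its call (0.707). Without dnIGF1R/Wnt1 replicate 1 so did AW112010 (0.118), Cdo1 (0.054), Lypd3 (0.142), Cldn11 (0.151), Hmcn1 (0.0523), Cd44 (0.256) and Cadm1 (0.207), and without replicate 2 AW112010 (0.0881), Cdo1 (0.0564) and Lypd3 (0.0962). Replicate 4 of dnIGF1R/Wnt1 held 64.9% of the 404 cells of the luminal-like cluster led by Prlr, Areg, Cited1 and Pcp4. DESeq2 called 5 genes, and none of these 10 among them. With 200 changed genes simulated among 8556, 12 unchanged genes were called and 2% of 2-fold and 62% of 4-fold changes were recovered. Free RNA in basal-like cells was estimated highest in Wnt1 replicate 3 (20.4%). No technical or biological explanation of these differences was tested.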

How the results depend on the processing

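The 8 added alternatives listed above were chosen after seeing the data, the others before. Away from left-out libraries, the edgeR count of changed genes stayed at 0 (1 in basal-like cells) in each class with library size only, stricter cells, doublets kept, at least 50 cells and both other seeds. The count of 0 changed shares held in every setting that kept all libraries. Where no cause is named, the cause was not tested. No paired analysis was possible because replicate numbers were given in accession order and pair nothing. Recovery of genes simulated with a 4-fold change was lowest in endothelial-like cells (52%), where depth and spread were not told apart. Many values turn on Wnt1 replicate 3.

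The clusters themselves moved with the random seed. Of the 36872 cells, 87.8% kept their class with seed 1 and 90.5% with seed 2. With seed 1 the share that kept its class was 71.5% of basal-like and 74.6% of lineage-not-named cells, and with seed 2 it was 89.2% of basal-like cells and 13.1% of fibroblast-like cells, while the pericyte-like class grew from 883 to 2524 cells.

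Of the 1618 values without a left-out library, 1348 kept their direction and side of the threshold, 56 lost a call, 73 gained one, 64 counts or values moved and 77 turned. With 1 library left out, 492 of 688 held, and the other numbers were 30, 84, 32 and 50.

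With an estimated correlation, list calls in epithelial-like cells were 0. With DESeq2, the count of genes was 145 in epithelial-like cells, 114 in luminal-like cells, 5 in basal-like cells, 17 in fibroblast-like cells, 14 in macrophage-like cells, 260 in whole tumor, 17 in pericyte-like cells, 54 in lineage-not-named cells and 5 for the difference between basal-like and luminal-like cells. Igf1r was at 0.007 in whole tumor.

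Without the filter on low counts, the edgeR count of genes was 394 in epithelial-like cells, 343 in luminal-like cells, 60 in basal-like cells, 40 in fibroblast-like cells, 42 in macrophage-like cells, 13 in endothelial-like cells, 2 in whole tumor, 56 in pericyte-like cells, 226 in lineage-not-named cells and 138 for the difference between basal-like and luminal-like cells. Cdh1 was at -0.038 in luminal-like cells, Igf1r was at -0.006 in pericyte-like cells and -0.001 in lineage-not-named cells and Insr was at -0.003 in lineage-not-named cells.

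With the length trend removed, the edgeR count of genes was 1 in luminal-like cells. Igf1r was at 0.033 in epithelial-like cells, 0.019 in luminal-like cells, 0.114 in fibroblast-like cells and 0.066 in whole tumor, Insr was at 0.036 in epithelial-like cells and 0.161 in endothelial-like cells, Cdh3 was at 0.019 in basal-like cells and Cdh1 was at 0.045 in lineage-not-named cells. With library size only, Cdh1 was at -0.208 in luminal-like cells, Insr was at -0.058 in basal-like cells and -0.131 in lineage-not-named cells and Igf1r was at -0.185 in pericyte-like cells and -0.131 in lineage-not-named cells. With genes left out that free RNA could supply, the edgeR count of genes was 1 in luminal-like cells and 1 in pericyte-like cells. Cdh1 was at -0.005 in luminal-like cells and Insr was at -0.001 in lineage-not-named cells. Counted among non-epithelial cells, the share of T cell-like cells was at -0.743. With the Acta1-led and neutrophil-like clusters out of the total, the share of lineage-not-named cells was at 0.312 and the share of pericyte-like cells was at 0.398. With the mixed clusters out too, the share of lineage-not-named cells was at 0.122 and the share of pericyte-like cells was at 0.202.

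With the looser filter, list calls in epithelial-like cells were 3. The edgeR count of genes was 0 in basal-like cells, 1 in pericyte-like cells and 19 for the difference between basal-like and luminal-like cells. Cdh1 was at -0.034 in luminal-like cells, Wnt1 was at 0.047 in luminal-like cells and -0.191 in pericyte-like cells, Igf1r was at 0.095 in fibroblast-like cells and -0.072 in lineage-not-named cells and Insr was at 0.037 in endothelial-like cells and -0.083 in lineage-not-named cells. The share of T cell-like cells was at -0.177 and the share of lineage-not-named cells was at 0.588. With the stricter filter, the edgeR count of genes was 15 for the difference between basal-like and luminal-like cells. Cdh1 was at -0.009 in luminal-like cells, Insr was at -0.003 in basal-like cells and 0.036 in endothelial-like cells and Igf1r was at -0.047 in pericyte-like cells and -0.049 in lineage-not-named cells. The share of lineage-not-named cells was at 0.123 and the share of pericyte-like cells was at 0.092.

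With doublets kept, list calls in epithelial-like cells were 3. Insr was at -0.029 in basal-like cells and -0.082 in lineage-not-named cells, Cdh3 was at -0.104 in macrophage-like cells, Wnt1 was at -0.312 in pericyte-like cells and Igf1r was at -0.037 in lineage-not-named cells. The share of lineage-not-named cells was at 0.266. With doublets removed at a fixed rate, list calls in epithelial-like cells were 3. The edgeR count of genes was 1 in fibroblast-like cells. Cdh1 was at -0.016 in luminal-like cells, Wnt1 was at 0.033 in luminal-like cells, Cdh3 was at 0.082 in basal-like cells and 0.317 in fibroblast-like cells, Igf1r was at 0.133 in fibroblast-like cells and -0.018 in lineage-not-named cells and Insr was at -0.084 in lineage-not-named cells. The share of T cell-like cells was at -0.061 and the share of macrophage-like cells was at -0.115. At resolution 0.5, list calls in epithelial-like cells were 3. Igf1r was at 0.042 in fibroblast-like cells and -0.088 in lineage-not-named cells, Cdh3 was at 0.64 in fibroblast-like cells, Cdh1 was at 0.184 in fibroblast-like cells, F10 was at 0.023 in macrophage-like cells and Insr was at -0.09 in lineage-not-named cells. The share of lineage-not-named cells was at 0.043 and the share of macrophage-like cells was at -0.099.

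With clustering seed 1, list calls in epithelial-like cells were 3. Igf1r was at -0.076 in pericyte-like cells and -0.038 in lineage-not-named cells, Wnt1 was at -0.071 in pericyte-like cells and Insr was at -0.134 in lineage-not-named cells. The share of lineage-not-named cells was at 0.251 and the share of pericyte-like cells was at 0.02. With clustering seed 2, list calls in epithelial-like cells were 3. Cdh3 was at 0.111 in basal-like cells, Wnt1 was at -0.35 in pericyte-like cells, Igf1r was at -0.008 in lineage-not-named cells and Insr was at -0.062 in lineage-not-named cells. The share of lineage-not-named cells was at 0.043. With the cluster led by Acta1 kept, list calls in epithelial-like cells were 3. Igf1r was at -0.071 in lineage-not-named cells and Insr was at -0.129 in lineage-not-named cells.

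Leaving out each library in turn, the count of changed genes ranged from 0 to 305 in epithelial-like, 0 to 477 in luminal-like, 0 to 386 in basal-like, 0 to 412 in fibroblast-like, 0 to 1442 in macrophage-like, 0 to 181 in endothelial-like, 0 to 876 in pericyte-like and 0 to 561 in lineage-not-named cells. List calls in epithelial-like cells ranged from 4 to 9, genes that differ between basal-like and luminal-like cells from 13 to 172, and changed shares from 0 to 2. Fits without a dnIGF1R/Wnt1 library gave 0 genes in each class, and whole tumor gave 0 throughout. The fits without each Wnt1 library called mostly different genes. Shared in the same direction were 16 in epithelial-like, 12 in luminal-like, 17 in basal-like, 25 in fibroblast-like, 44 in macrophage-like and 8 in endothelial-like cells, against 5.62, 5.97, 10.3, 8.25, 53.8 and 2.53 for independent lists, a value that leaves out the dnIGF1R/Wnt1 libraries that both fits share.

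In the same fits Igf1r ranged from -0.089 to 0.054 in epithelial-like cells, -0.436 to 0.086 in fibroblast-like cells, -0.077 to 0.062 in whole tumor, -0.135 to 0.239 in pericyte-like cells and -0.058 to 0.123 in lineage-not-named cells. Insr ranged from -0.113 to 0.066 in epithelial-like cells, -0.212 to 0.014 in luminal-like cells, -0.477 to 0.429 in endothelial-like cells, -0.525 to 0.017 in pericyte-like cells and -0.103 to 0.15 in lineage-not-named cells. Cdh1 ranged from -0.311 to 0.2 in epithelial-like cells, -0.191 to 0.247 in luminal-like cells, -0.4 to 0.022 in basal-like cells, -1.654 to 0.261 in macrophage-like cells, -1.28 to 0.118 in endothelial-like cells, -0.334 to 0.142 in whole tumor and -0.319 to 0.321 in lineage-not-named cells. Cdh3 ranged from -0.327 to 0.245 in luminal-like cells, -0.213 to 0.203 in basal-like cells, -0.728 to 0.354 in fibroblast-like cells, -0.627 to 2.251 in macrophage-like cells and -0.28 to 1.21 in endothelial-like cells. Wnt1 ranged from -0.313 to 0.244 in luminal-like cells and -0.167 to 1.084 in pericyte-like cells. For Wnt1, macrophage-like cells gave -1.841 to 0.525. Igf1 ranged from -0.109 to 1.614 in macrophage-like cells and -0.162 to 0.526 in whole tumor. For Areg, basal-like against luminal-like, the difference ranged from -3.684 to 2.405. The log2 difference ranged from -3.66 to 0.611 in the share of T cell-like cells, -1.274 to 0.635 in the share of basal-like cells, -0.324 to 0.092 in the share of lineage-not-named cells, -5.99 to 7.01 in the share of neutrophil-like cells and -0.222 to 0.134 in the share of pericyte-like cells.

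Whole tumor without mixed clusters gave 0 genes, as did epithelial-like and lineage-not-named cells with the cluster led by Acta1 kept. Genes of T cell-like cells and whole tumor at resolution 0.5, with 50 cells or with free RNA genes left out, and pericyte-like cells at resolution 0.5, which formed no such class, were not run.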

Other observations

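The tests of the pericyte-like and lineage-not-named classes, the search for genes shared by all classes, the length correction, the test of genes near Rnaset2a and the free RNA test by hemoglobin genes were chosen only after results had been seen. Across the 7 classes that share no cells, 35 of 7669 genes had an unadjusted p under 0.05 and the same direction in each, 32 higher and 3 lower in dnIGF1R/Wnt1. Beside Rnaset2a, the higher ones included Ost4 (log2 1.45 to 1.84), Gstp1 (1.31 to 1.59), Dynlt1f (1.099 to 1.99), the glycolytic Gapdh (0.74 to 1.185) and the respiratory chain gene Sdhd (1.05 to 1.31). Camk1d was lower (-1.91 to -1.32), and so were Gm42418 (-1.97 to -1.17) and Gm26917 (-2.065 to -0.91), neighboring gene models on chromosome 17. The higher genes had a median genomic length of 6.79 kb, the 3 lower ones of 3.33 kb, and all 7669 genes of 28.2 kb. The classes share libraries and are not independent.

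Epithelial cells without a named lineage, 9133 in all, differed between the genotypes in cell cycle and milk genes as lists. The class joins 4 clusters of unequal makeup: 87.8% of the 2480 cells of one came from Wnt1 replicate 3, and 34.7% of the 2395 cells of another from dnIGF1R/Wnt1 replicate 4, so these values mix makeup with expression. Proliferation genes were higher in 21 of 27 members, with Ube2c at log2 1.61 and Aurkb at 1.52 (camera adjusted p = 3.19e-07; adjusted p = 0.773 with an estimated correlation), and 4 passed adjusted over the list alone. Alveolar luminal and milk genes were lower in 12 of 14 members, with a median of -0.67 and with Elf5, a transcription factor of the alveolar lineage, at -1.43, and 1 fell adjusted over the list alone (0.00534; adjusted p = 0.773 with an estimated correlation). Oxidative phosphorylation (6.75e-05), glycolysis (7.45e-04) and oxidative stress genes (0.0322) were called upward and matrix genes downward (0.0434), with 0, 0, 1 and 0 members passing adjusted over the list alone (adjusted p = 0.773 with an estimated correlation for each). Krt8, a luminal keratin gene, was at 42.25 and 13.4 CPM in Wnt1 and dnIGF1R/Wnt1 (log2 -1.68 ± 0.25 (SE), edgeR adjusted p = 0.352), Plet1 at 14.3 and 4.41 CPM (-1.66) and Ism2 at 4.51 and 0.378 CPM (-3.73), while Rnaset2a was at 27.7 and 104.9 CPM (1.93 ± 0.26, adjusted p = 0.272), Tagln3 at 4.31 and 16.7 CPM (2.004) and Phpt1 at 39.9 and 121.2 CPM (1.61). Of 14048 genes, 0 passed the edgeR test, 1074 had an unadjusted p under 0.05 and DESeq2 called 54. The edgeR count was 561 without Wnt1 replicate 2 and 507 without Wnt1 replicate 3. Without Wnt1 replicate 2 the adjusted p was 0.137 for proliferation, 0.0755 for oxidative phosphorylation and 0.103 for oxidative stress, and without Wnt1 replicate 3 it was 0.124 for oxidative stress while milk genes (0.716) and matrix genes (0.748) turned the other way. The milk call was also lost without dnIGF1R/Wnt1 replicate 1 (0.107) and with clustering seed 1 (0.332), and oxidative stress (0.0769) and matrix genes (0.0563) without dnIGF1R/Wnt1 replicate 4 and with the length trend removed (0.0536 and 0.0591). These 2 held in 9 and 10 of 16 alternatives, and matrix genes also turned with free-RNA genes left out (0.653).

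Pericyte-like cells, 883 in all, were higher in proliferation genes in 20 of 23 members, with Birc5 at log2 1.61 and Cdk1 at 1.85 (camera adjusted p = 2.07e-05; adjusted p = 0.833 with an estimated correlation), though without Wnt1 replicate 2 the list turned the other way (0.634). Oxidative phosphorylation (2.07e-05), glycolysis (2.54e-05), cholesterol synthesis (0.047) and oxidative stress genes (0.0488) were called upward (adjusted p = 0.833 with an estimated correlation for each), with 6, 3, 0 and 1 members passing adjusted over the list alone and 0 for proliferation. Cholesterol synthesis lost its call without Wnt1 replicate 2 (0.533) and dnIGF1R/Wnt1 replicate 4 (0.643), and oxidative stress without Wnt1 replicates 2 and 3 (0.39 and 0.0846) and dnIGF1R/Wnt1 replicates 2 and 4 (0.0692 and 0.155). Cholesterol synthesis held in 5 of 13 alternatives and turned the other way in 3, with the looser cell filter (0.52), with doublets kept (0.519) and with clustering seed 2 (0.472), and oxidative stress held in 3 of 14. Rnaset2a was at 25.4 and 129.6 CPM (log2 2.355 ± 0.29 (SE), edgeR adjusted p = 0.0831), Spry2, an inhibitor of receptor tyrosine kinase signalling, at 39.7 and 115.3 CPM (1.56 ± 0.29), and Bex4 at 17.1 and 54.1 CPM (1.703). Cmss1 was at 326.9 and 111.1 CPM (-1.56), and the epithelial genes Krt6a at 29.1 and 1.797 CPM (-3.78) and Sbsn at 32.8 and 10.8 CPM (-1.59). The upper estimate of free RNA in these cells was 17.14 and 30.98% in Wnt1 replicates 2 and 3 and 26.2, 28.01 and 18.46% in dnIGF1R/Wnt1 replicates 1, 2 and 4, and Krt6a was at 36.5 and 21.8 CPM in the Wnt1 libraries. Of 9166 genes, 0 passed the edgeR test, 770 had an unadjusted p under 0.05 and DESeq2 called 17 and gave no adjusted p for 7822. The edgeR count was 298 without Wnt1 replicate 2 and 876 without Wnt1 replicate 3.

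Rnaset2a was higher in dnIGF1R/Wnt1 in all 9 tested classes, some of which share cells, and the log2 differences lay between 1.93 and 2.355. Reads counted for its paralog Rnaset2b do not account for this: both genes summed still differed by 1.899 ± 0.20 (log2, SE) in epithelial-like cells. Rnaset2b was at 2.446 CPM in Wnt1 and 2.14 to 3.105 in dnIGF1R/Wnt1. Reads in neither count were not tested. A genomic segment near Rnaset2a that differs between the animals, by strain or copy number, may be a source: of the 55 tested genes within 5 Mb, 5 (9.09%, exact 95% interval 3.02 to 20%) had an unadjusted p under 0.05, against 1282 of 15990 others (8.02%; one-sided Fisher exact p = 0.454). All 5 were higher, with Dynlt1f, 1 of the 35 genes above, at log2 1.603. A variant in 1 gene would leave its neighbors unchanged. Such a segment and an effect of dnIGF1R cannot be told apart, as the labels do not give the background of the animals.

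Oxidative phosphorylation genes were called upward by camera in all 9 tested classes, which share libraries and some cells, with median log2 differences of 0.31 to 0.51. A gene length trend between the libraries is argued against as the whole cause. With it removed the list was called in each class (largest adjusted p = 0.0357), with medians of 0.29 to 0.59. Sequencing depth could still contribute: between libraries paired by median UMIs per cell, which stayed unequal, the median was 0.61 ± 0.25 (SE) for Wnt1 replicate 2 and dnIGF1R/Wnt1 replicate 4 (7950 and 4303 UMIs), with 12 of 17 members higher (70.6%), and 0.19 ± 0.10 for Wnt1 replicate 3 and dnIGF1R/Wnt1 replicates 1 and 2 (1852 against 2296 and 2012), with 14 of 17 higher (82.4%). The bound set before the test asked for more higher members than the first pairing had, so depth and genotype cannot be told apart here. RNA quality and capture were not tested and stay open, beside lower Gm42418, Gm26917 and Camk1d in each class that shares no cells, and with an estimated correlation each call was lost, so an effect of genotype remains a hypothesis.

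In fibroblast-like cells, epithelial adhesion genes were lower in dnIGF1R/Wnt1 with a median log2 of -0.78, a call lost without Wnt1 replicate 3 (camera adjusted p = 0.594). Free epithelial RNA in Wnt1 libraries is a candidate source. Its upper estimate in these cells of Wnt1 replicate 3, 50.6% of UMIs, rests on markers they should lack, whatever their source. A test that set free RNA by hemoglobin genes was void, implying 171% of those UMIs. Free RNA and a difference in these cells cannot be told apart.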
